A study of Drosophila melanogaster with 6 samples.

How the data were processed

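Gene expression was measured in whole female third-instar larvae of Drosophila melanogaster on 6 Affymetrix Drosophila Genome 2.0 arrays, 1-colour arrays on which a set of short probes, a probeset, reads each transcript. RNA came from 3 preparations of larvae that carried neither roX1 nor roX2 and from 3 preparations of larvae of the same mutant genotype with a roX1 transgene driven by the hsp83 promoter. Each preparation pooled 50 larvae, and the preparations were independent, per the labels' design text. Both genotypes carry a further transgene marked w+, per the labels, and the insertion sites of the transgenes are not given in the sources used here. The mutants and controls therefore differ by the transgene and by whatever else differs between the stocks, which the labels do not describe.

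The deposited values are log2 expression values, 1 per probeset and array. The authors corrected the background, normalized the arrays to each other and summarized the probes by robust multi-array average (RMA), per the labels' design text and the submitters' processing notes, with no version given. That text also names a filter on present and absent calls. The table analysed here holds 18952 probesets, including 183 control probesets, and no calls, so a filter on level took its place. The medians of the 6 arrays lay between 5.41 and 5.45 and their values between 2.40 and 14.5. RMA brings the arrays to a common distribution, so a change shared by most transcripts would not be seen in these values. For arrays the number of arrays limits the precision, here 3 against 3.

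Probesets were named through the platform annotation. Of the probesets, 13647 had 1 gene symbol, 402 had several and 4720 were not listed and stay unnamed here. Through the gene number, 13544 of the named probesets were matched to the RefSeq gene table of the assembly Release 6 plus ISO1 MT, which was used only for symbols, chromosome arm and gene order. No probeset is listed there under roX1, roX2, w or Hsp83, so their levels were not analysed here and the planned check of the labels by the roX1 level was not run.

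The control probesets and the 40% of the others with the lowest mean over all 6 arrays were left out, which left 11262 probesets with a mean of at least 4.51. Differences, mutant minus control, were tested with limma version 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. All adjusted p-values of single genes are from this fit. For gene groups each gene was represented by its brightest tested probeset with 1 gene name, which gave 8883 genes, 8852 of them with a chromosome arm. A chromosome class was summarized by the median log2 change of its genes minus that of the comparison genes of 2L, 2R, 3L and 3R, and the same median difference was taken on each array and compared by an exact two-sided permutation test, whose smallest possible p is 0.1. The pericentric class holds the measured genes among the 80 genes nearest the centromere on each of those arms. Sets were tested with limma's camera, with a preset correlation of 0.01 as the main test and an estimated correlation beside it, and with fry. Neighbouring calls were compared with 10000 random draws of as many tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

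Before the data were examined, 24 gene lists, the main tests, most alternatives and the rule for named genes were fixed. The comparisons between chromosome arms, the counts of called genes per arm under the alternatives and the second chromosome as comparison set were added afterwards. The lists are dosage compensation machinery, heterochromatin and chromosome 4 regulators, pericentric and chromosome 4 genes by symbol, sex determination, male germline, female germline and Y-linked genes, fat body, gut, salivary gland, muscle, neuron and hemocyte markers, larval cuticle, ecdysone response, heat shock, immune response, detoxification, ribosomal proteins, proteasome, DNA replication, mitochondrial respiration, and genes near roX1 or in the transgene. Set tests needed at least 5 tested genes. The rule names roX1, roX2, w and Hsp83 whatever they do, the 10 largest rises and 10 largest falls among genes that were called and whose 3 mutant values all lay on one side of the 3 control values, and up to 3 members of each list and chromosome class with the smallest p. If fewer than 5 genes passed in a direction, the 5 with the smallest p were to be given as values that did not pass. Genes named outside this rule are said to be so.

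The steps were tested on simulated data with the levels and spread of these arrays, with 200 of 18769 probesets changed. The simulated noise was independent between probesets and held no outlying array, so the shares below may be too favourable for the real arrays. In the mutant against control comparison, with 11262 probesets tested, 37.3% of the 67 simulated changes of 0.5 on the log2 scale were called, 91.0% of the 67 changes of 1 and 93.9% of the 66 changes of 2, and 3.27% of the calls were false. The alternatives were no filter and a filter on the lowest 60%, quantile normalization, median centring, a replicate block, eBayes with trend and robust settings, array weights, other thresholds, a plain Student test, other ways to represent a gene, other class limits and leaving out each array.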

Results

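The roX1 and roX2 RNAs are long noncoding RNAs of the dosage compensation complex, which acts on the X chromosome of male flies. The series asks whether their loss changes gene expression in females. Whole third-instar female larvae without roX1 and roX2 were compared with larvae of the same mutant genotype that carried a roX1 transgene under the hsp83 promoter. Each group had 3 arrays, and each array received RNA of 50 larvae. Values are log2 RMA expression values, and differences are mutant minus control. Correlations across probesets lay between 0.9903 and 0.9976 within groups and between 0.9903 and 0.9958 between groups. The levels of roX1, roX2, w and Hsp83 were not analysed here, so the targeted gene does not check the labels.

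Few genes were called as different between mutant and control females, and the largest called differences were in single genes of varied function. The transcript of mthl8, a methuselah-like receptor gene, rose 8.07-fold, from 4.81 ± 0.39 to 7.83 ± 0.25 (mean ± SD, n = 3 per group; limma adjusted p = 0.0035). A second, dimmer mthl8 probeset rose 1.66-fold (log2 change 0.73; limma adjusted p = 0.0149). The transcript of eIF4E3, a cap-binding translation factor gene used in the male germline, rose by 2.84 on the log2 scale (SE 0.18; limma adjusted p = 0.0028). LysX, a lysozyme gene of the digestive tract, fell from 11.8 ± 0.14 to 9.96 ± 0.12 (log2 change -1.86, SE 0.10; limma adjusted p = 0.0015). Lkr, the receptor of the neuropeptide leucokinin, fell 3.51-fold (log2 change -1.81, SE 0.09; limma adjusted p = 0.0013). In all, 62 of 11262 tested probesets were called at an adjusted p under 0.05 with limma, 40 higher and 22 lower in the mutant, which is 0.551%. At an unadjusted p under 0.05 there were 1014, or 9.0%. A split that mixed the groups, mutant replicates 1 and 2 with control replicate 1 against the rest, gave 905.

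The other large rises were of CG31226 (log2 change 2.60), CG13461 (2.34), CG42369 (2.01), CG32055 (1.99), CG3397 (1.61), CG32379 (1.5), CG16713 (1.43) and CG11357 (1.39), with limma adjusted p-values between 0.0035 for CG32379 and 0.0399 for CG13461. The control means of eIF4E3 (4.22), CG31226 (3.42), CG32055 (4.39) and CG32379 (4.23) lay below 4.51, the lowest mean of a tested probeset, so the sizes and order of these rises are uncertain. Among genes read by their brightest probeset, the largest falls were of CG3857 (-2.36 on the called probeset and -0.060 on its second), the only called X-linked gene, and CG42633 (-2.34), with limma adjusted p-values of 0.0013 and 0.0014. CG6865 (-1.58), the noncoding RNA gene lncRNA:CR32368 (-1.33), CG4080 (-1.25), the iodotyrosine deiodinase gene Iyd (-0.98), CG7542 (-0.95) and GstZ1 (-0.87), a glutathione transferase of the zeta class, fell as well, with limma adjusted p-values from 0.022 to 0.0494. The calls of CG6865, lncRNA:CR32368 and Iyd were lost when any 1 of the 6 arrays was left out, that of GstZ1 in 5 of the 6 such fits and those of CG4080 and CG7542 in 4; CG6865 and CG7542 also lost theirs under quantile normalization. Of the rises, CG32055 lost its call in 5 of the 6 fits, CG13461, CG42369, CG3397 and CG11357 in 4 and CG16713 in 3. The calls of mthl8, eIF4E3, CG32379, LysX, Lkr, CG3857 and CG42633 held in all 6, with limma adjusted p-values of at most 0.0401, and that of CG31226 in the 4 in which it was tested. The 62 called probesets had 51 with 1 gene name and stood for 47 genes represented by their brightest probeset, 33 higher and 14 lower. On all 62 the 3 mutant values lay on one side of the 3 control values, which was so for 16.3% of all tested probesets and is 10% by chance. The number of called probesets fell to between 12 and 31 when mutant replicate 1 (17), mutant replicate 2 (12), mutant replicate 3 (27), control replicate 2 (31) or control replicate 3 (20) was left out, and was 84 without control replicate 1.

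**Figure D1:**
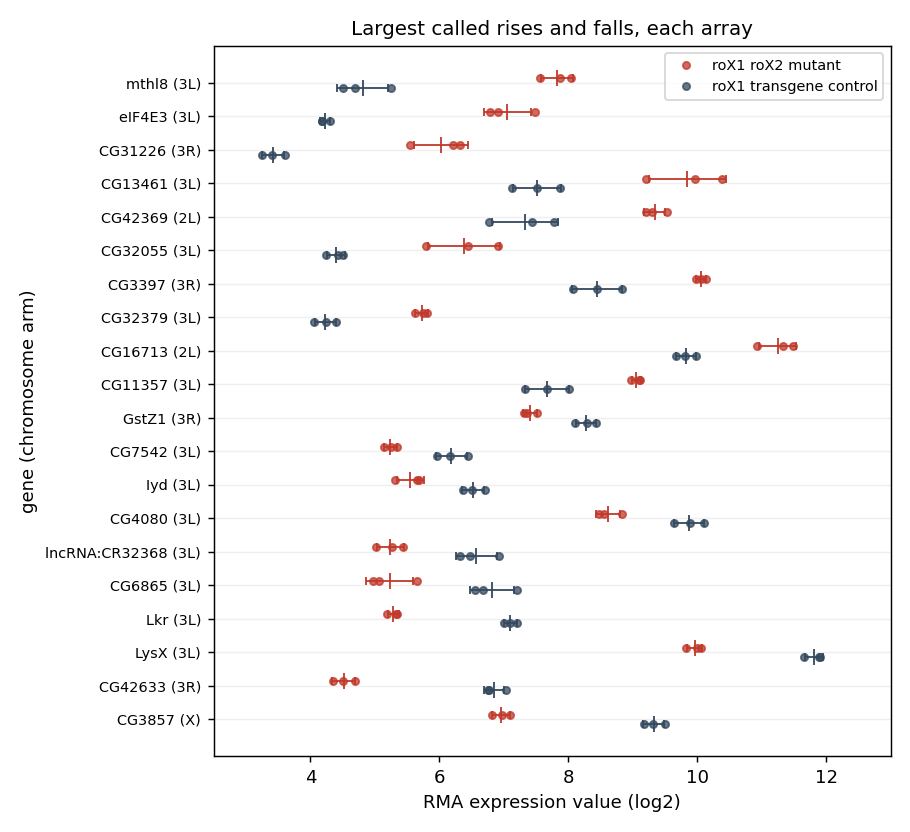
RMA expression values (log2, x axis) of the 10 largest called rises and 10 largest called falls among genes read by their brightest named probeset (y axis, with the chromosome arm), where each dot is 1 array, the tick is the group mean and the bar is ± 1 SD of 3 arrays. For each gene shown, the 3 mutant arrays lie on one side of the 3 control arrays.

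The called genes were unevenly spread over the chromosomes, and 28 of 47 lay on 3L, the left arm of the third chromosome. Of 1764 tested genes on 3L, 28 were called (1.59%), 17 higher and 11 lower in the mutant. The number on 3L fell to 6 of 12 called genes without mutant replicate 1, 6 of 9 without mutant replicate 2, 12 of 18 without mutant replicate 3, 11 of 19 without control replicate 2 and 8 of 14 without control replicate 3, and was 36 of 66 without control replicate 1 and 88 of 184 with array weights. With all 6 arrays those on 3L include mthl8, eIF4E3, LysX, Lkr, CG13461, CG32055, CG32379, CG11357, CG6865, lncRNA:CR32368, CG4080, Iyd and CG7542. On the right arm, 3R, 11 of 2237 genes were called (0.492%), among them CG31226, CG3397, CG42633 and GstZ1. On 2L 4 of 1573 genes were called, on 2R 2 of 1828, on X 1 of 1394 and on chromosome 4 1 of 56. The share on 3L was higher than the 18 of 7032 genes on 2L, 2R, 3R and X together (odds ratio 6.28, Fisher's exact p = 1.5e-09, adjusted 1.1e-08 over 7 such comparisons, chosen after the calls were seen). The 3R share against 6 of 3401 genes on 2L and 2R did not pass after adjustment (Fisher's exact p = 0.0456, adjusted 0.0638). Fisher's exact test, here and below, treats genes as independent. All genes were read on the same 6 arrays, so its p-values do not measure variation between arrays. No 2 called genes were direct neighbours among the tested genes, against a mean of 0.246 pairs in random draws (one-sided permutation p = 1). Within 5 places there were 3 pairs against a mean of 1.23 (one-sided permutation p = 0.126).

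**Figure D2:**
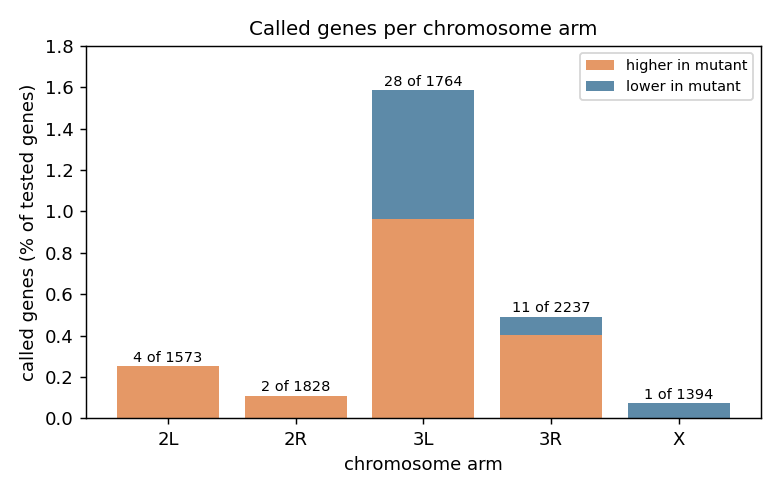
Called genes as a percentage of the tested genes of each large chromosome arm (y axis), split into genes higher and lower in the mutant, with the called and tested numbers above each bar. The highest bar is 3L with 28 of 1764 genes and the lowest is X with 1 of 1394; chromosome 4, with 56 tested genes, is not drawn.

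X-linked genes, the class that roX RNAs act on in males, had a median change slightly below that of autosomal genes. The only called X-linked gene was CG3857, which was 5.15-fold lower in the mutant (6.96 ± 0.14 against 9.33 ± 0.16, n = 3 per group). The second tested CG3857 probeset had a log2 change of -0.060 (limma adjusted p = 0.932). The values next in p were those of CG32625 (log2 change 1.25, limma adjusted p = 0.120) and CG12237 (-0.37, limma adjusted p = 0.125), which did not pass. The median log2 change of 1394 X-linked genes was -0.037 and that of 7402 autosomal genes 0.0029, a difference of -0.040. Per array, the class median relative to autosomal genes was -0.022 ± 0.023 in mutants and 0.020 ± 0.034 in controls (n = 3 per group; exact two-sided permutation p = 0.2). Limma's camera gave p = 0.0095 (adjusted 0.0142 over the 3 classes) with the preset correlation and p = 0.226 (adjusted 0.598) with an estimated correlation. Camera's call was lost without mutant replicate 1 (difference -0.026), without control replicate 1 (-0.022) and with no filter on dim probesets (-0.024, adjusted p = 0.0606). Fewer genes were called on X than on the autosomal arms, 1 of 1394 against 45 of 7402 (Fisher's exact p = 0.0070, adjusted 0.0211), and the difference from the second chromosome alone, 6 of 3401, did not pass (Fisher's exact p = 0.681, a comparison added after the calls were seen).

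Genes of chromosome 4, a small and largely heterochromatic chromosome, had a median difference of 0.014 from autosomal genes over 56 tested genes (limma's camera p = 0.588, and p = 0.894 with an estimated correlation; exact permutation p = 1). Rnf11, a RING finger gene, was the only called gene of this chromosome and rose 1.76-fold (7.53 ± 0.16 against 6.71 ± 0.15, n = 3 per group; limma adjusted p = 0.0419). A second tested Rnf11 probeset had 0.36 (limma adjusted p = 0.508), and the call was lost when any 1 array was left out. Zip102B, a zinc transporter gene, had a log2 change of -0.44 (limma adjusted p = 0.396) and CG11155 one of 0.18 (limma adjusted p = 0.556). The sign of the difference turned to -0.066 without mutant replicate 1 and to -0.015 without control replicate 3. Without mutant replicate 3 it was 0.068 and passed camera's threshold (adjusted p = 0.0469) with the preset correlation alone.

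Genes next to the centromeres of the large autosomes had a median log2 change of 0.086, which was 0.085 above that of 7278 other autosomal genes, over 124 tested genes. None of them was called; the smallest p-values belonged to flip (log2 change 0.42, limma adjusted p = 0.193), CG3107 (0.335, limma adjusted p = 0.393) and lncRNA:CR43242 (0.32, limma adjusted p = 0.458). Limma's camera gave p = 6.8e-05 (adjusted 2.0e-04) with the preset correlation and p = 0.399 (adjusted 0.598) with an estimated correlation of 0.317. The class median was 0.043 ± 0.079 in mutants and -0.046 ± 0.012 in controls (n = 3 per group; exact permutation p = 0.3), and mutant replicate 3, at -0.043, lay with the controls. Without mutant replicate 2 the difference was 0.050. The 21 tested pericentric genes of the symbol list gave a difference of 0.053 (camera p = 0.0435, which did not pass after adjustment over the 3 classes, 0.0652, and p = 0.573 with an estimated correlation).

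**Figure D3:**
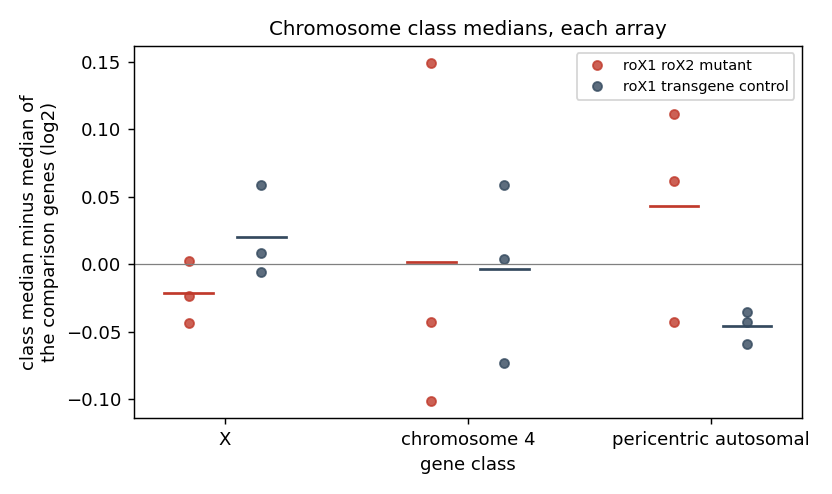
Median of each chromosome class minus the median of its comparison genes on each array (log2, y axis), after each gene was centred on its mean over the 6 arrays; dots are arrays and lines are group means. The groups overlap on all 3 classes, with pericentric values of 0.062, 0.111 and -0.043 in mutants and -0.059, -0.043 and -0.035 in controls.

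Among the 24 fixed lists, single detoxification, gut and cuticle genes were called, and no list passed limma's camera in the main fit of all 6 arrays. Of 82 tested cytochrome P450 and glutathione transferase genes, Cyp6d5 (log2 change 0.63, limma adjusted p = 0.0159) and GstE1 (0.82, limma adjusted p = 0.0461) rose and Cyp12c1 (-0.74, limma adjusted p = 0.0112) fell, and 6 passed when adjusted over the list alone. The GstE1 call was lost when any 1 array was left out and under quantile normalization, and those of Cyp6d5, Cyp12c1 and Cpr67B, a cuticle gene, in 5 of the 6 fits with 1 array left out. Of 42 gut and digestive enzyme genes, LysX fell, and another lysozyme gene, LysP, had a log2 change of 1.21 (limma adjusted p = 0.0896); these 2 passed adjusted over the list alone. Of 23 larval cuticle genes, Cpr67B rose 1.51-fold (limma adjusted p = 0.0250) and Lcp65Af had a log2 change of 1.83 (limma adjusted p = 0.139), and 2 passed adjusted over the list alone. In the main fit no list of the 21 tested passed limma's camera (smallest adjusted p = 0.178, and 0.926 with an estimated correlation), and 4 lists had an unadjusted p under 0.05. With all 6 arrays, muscle passed under the replicate block, and pericentric genes by symbol, proteasome and mitochondrial respiration passed with array weights. These did not pass with an estimated correlation. The detoxification list, with a median of 0.098, passed camera without mutant replicate 1 (median 0.125), mutant replicate 2 (0.095), control replicate 2 (0.121) or control replicate 3 (0.183), and larval cuticle, with 0.146, without mutant replicate 1 (0.334) or mutant replicate 2 (0.211), in no case with an estimated correlation. Fry found 0 lists that moved one way (smallest adjusted p = 0.872) and 3 with changes in either direction: detoxification (adjusted p = 0.0030), gut (0.0239) and DNA replication (0.0279). Median and mean differed in sign for the gut list (0.018 and -0.018) and for sex determination, with a median near 0 and a mean of 0.067. The detoxification list also stood apart on control replicate 1, where its median was -0.32 from the mean of the 6 arrays, against 0.022 to 0.077 on the other 5. Every fit in which this list passed camera kept that array. Over all 6 fits with 1 array left out its median ran from -0.038 to 0.183, and that of larval cuticle from 0.0043 to 0.334.

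Genes of the dosage compensation machinery were not called among 12 tested members. JIL-1, a histone kinase of this complex, had a log2 change of -0.44 (limma adjusted p = 0.347), lola -0.15 and msl-2, the male-specific subunit, -0.13, and the list's median was -0.045 (camera adjusted p = 0.390). Among 12 heterochromatin and chromosome 4 regulators, the histone methyltransferase gene E(z) had 0.24 (limma adjusted p = 0.437) and HDAC1 -0.17 (camera adjusted p = 0.736 for the list). Sex determination genes had a median change near 0 over 12 members (camera adjusted p = 0.565), with 0.30 for fru and 0.17 for the sex switch gene Sxl, neither of which passed. Of the 4 tested male germline genes, Mst87F had -0.55 (limma adjusted p = 0.176, 0.0098 adjusted over the list alone) and CycB3 -0.31. The 6 probesets of 4 Y-linked genes were below the level filter in both groups, with group means from 2.52 to 4.36. Female germline genes had a median of 0.043 over 6 members (camera adjusted p = 0.379), with 0.24 for bam. The 4 tested genes of the list around roX1 and the transgene were not called, with -0.24 for yin, -0.17 for Ubr3, -0.11 for Fur2 and -0.051 for CG11695.

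No member of the remaining lists was called. Muscle genes had a median change of 0.15 over 15 members (camera adjusted p = 0.178, and 0.926 with an estimated correlation), with 0.70 for sls and 0.75 for Mlc2, and their median was -0.41 on control replicate 1 and 0.37 on mutant replicate 3. They passed camera without mutant replicate 1 (median 0.278), mutant replicate 2 (0.205), control replicate 2 (0.186) or control replicate 3 (0.25). These fits all kept control replicate 1, and the lowest median of muscle genes with 1 array left out was 0.040. Fat body and mitochondrial respiration genes passed without mutant replicate 1 (0.074 and 0.092), hemocyte and mitochondrial respiration genes without control replicate 2 (-0.166 and 0.119), proteasome genes without control replicate 1 (0.088) and the pericentric symbol list without mutant replicate 3 (0.157). None of these passed with an estimated correlation. Fat body genes had 0.042 over 11 members (camera adjusted p = 0.248), with 0.28 for Fbp1, 0.43 for Desat1 and 0.47 for FASN1. Hemocyte genes had -0.11 over 12 members (camera adjusted p = 0.276), with -0.98 for PPO2 and -0.81 for PPO1, the prophenoloxidases of crystal cells, neither of which passed. Immune response genes had -0.11 over 22 members (camera adjusted p = 0.345), and the antimicrobial peptide genes DptB and Def had -1.61 and -0.60 (limma adjusted p = 0.296 and 0.423). Medians were 0.043 for 14 salivary gland genes, -0.071 for 18 ecdysone response genes, -0.036 for 16 neuron genes and 0.040 for 10 heat shock genes. The largest single values there were 0.73 for ng1, 0.54 for MsrA, -0.43 for Syn and 0.70 for Hsp26. Medians were 0.0078 for 38 ribosomal protein genes, 0.011 for 28 proteasome genes, -0.029 for 24 DNA replication genes and 0.043 for 24 mitochondrial respiration genes. Camera adjusted p-values of these 8 lists were between 0.390 and 0.581. The 37 tested chromosome 4 genes of the symbol list had a median of 0.013 (camera adjusted p = 0.581).

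RNA quality was read from control probesets at the ends of the actin and GAPDH transcripts, where a larger excess of 3' over 5' signal goes with more degraded RNA. The excess was larger by 0.15 for actin in the mutants. The actin difference between 3' and 5' probesets was 0.871 ± 0.090 in mutants and 0.721 ± 0.021 in controls (n = 3 per group; exact permutation p = 0.1, the smallest possible). For GAPDH it was 1.38 ± 0.13 and 1.38 ± 0.033 (n = 3 per group; exact permutation p = 1). Control replicate 1 stood apart on the first principal component of the tested probesets (40.8% of the variance), at 32.6 against -10.6 to -2.67 on the other arrays.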

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

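Signals in control probesets that no comparison above used were higher in mutant than in control arrays, and 3 patterns are weighed here. All tests on 3L, the spike-in test and the splits for the chromosome classes were chosen after the result was seen; the level, length and single-array tests of the pericentric genes and the split test of called probesets were set before.

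The hybridization controls, transcripts added to each sample after labelling, were brighter by 0.269 on the log2 scale in mutant arrays (9.91 ± 0.092 against 9.64 ± 0.11, n = 3 per group; exact permutation p = 0.1, the smallest possible). All 18 of their probesets were higher, by 0.13 to 0.41. The 18S ribosomal RNA probeset was brighter by 0.690 (7.30 ± 0.26 against 6.61 ± 0.32, n = 3 per group; exact permutation p = 0.1). The 6608 tested probesets between 7.14 and 13.1 had a median change of 0.0031, but RMA brings the arrays to a common distribution and so holds that median near 0. Brightness or normalization of the arrays therefore stays open. A different amount of added control, a hybridization batch that followed the groups or a difference in the larvae was not tested.

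Of 47 called genes, 28 lay on 3L. The roX1 transgene is the one that differs between the groups, and its site is not given in the sources used here. If the called genes surrounded its insertion, they would fill few of 20 equal stretches of the arm. They lay in 12, although random draws of 28 genes filled 15.3 on average and 2.26% of draws as few as 12. Counted toward the centromere, they ran from place 1 to place 1453 of 1764 tested genes. The part of the arm next to the centromere therefore held none. Loss of roX RNA acting on X-linked genes predicts calls on X, where 0.0717% of tested genes were called, against 0.608% on the autosomal arms. That autosomal share includes the 28 genes on 3L, so the lower share on X is no independent evidence. Against 0.176% on the second chromosome the difference did not pass (Fisher's exact p = 0.681). Sequence variants under single probesets were not decided. Of 3 other tested probesets of 3 genes of 3L with a called probeset, 1 (33.3%) changed the same way by at least 0.5 times as much. Over all genes with a called probeset 1 of 12 did, while 10 of the 12 changed in the same direction. These counts include CG32369 on 3L and pyd and Antp on 3R. The brightest probeset of these genes was not called, so they are not among the 47. Stock and transgene differ together, so a strain difference linked to 3L and a direct effect of roX RNA on 3L genes cannot be separated. Both predict what uncalled 3L genes showed, more unadjusted p-values under 0.05 (12.3% against 7.71% on the other large arms, Fisher's exact p = 6.3e-09). Uncalled genes of 3R, which is among those other arms, had 10.4% against 6.66% on the second chromosome (Fisher's exact p = 9.2e-07). The excess was therefore not confined to 3L. These Fisher's tests treat genes of the same arrays as independent, so their p-values do not measure variation between arrays.

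Pericentric autosomal genes had a median 0.085 above and X-linked genes one 0.040 below their comparison genes, differences that passed camera with the preset correlation and not with an estimated one (p = 0.399 and 0.226; exact permutation p = 0.3 and 0.2), with mutant replicate 3 among the controls in both classes. Level and gene length were weighed as sources of the pericentric difference. For 10000 random lists of the same size and level, the share as high was 0.01%, the smallest they can give. The highest of their medians was 0.0651, below the 0.086 of the pericentric genes. For 10000 length-matched lists the share was also 0.01%, with a highest median of 0.0468. Such lists treat genes as independent, while the estimated correlation among the pericentric genes was 0.317. The spread of the lists may therefore be too narrow, and the shares alone exclude neither explanation. Correlation does not move the centre of the lists, however. That centre was 0.0030 for level and -0.023 for gene length, against 0.086 for the pericentric genes. Genes of the same level or length did not share the difference, which argues against both as its sources. Whether the difference exceeds the variation between arrays stays undecided. Leaving out no single array took the pericentric difference away, as the lowest such value was 0.050, without mutant replicate 2. Without mutant replicate 3 it was 0.1265, so its size depended on single arrays. The correlation among these genes and why mutant replicate 3 lay with the controls stay open.

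The 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. The real split called 62 probesets, 1 of 10 splits reached that number and the highest of the others called 2. The number at an unadjusted p under 0.05 set the real split less apart. It was 1014 there, 905 for mutant replicates 1 and 2 with control replicate 1, and between 118 and 691 for the remaining splits. For X the real size was 0.040, reached by 3 splits, and the highest other 0.053. For chromosome 4 it was 0.014, reached by 9 splits, and the highest other 0.145. For pericentric genes it was 0.085, reached by 3 splits, and the highest other 0.1, from mutant replicates 1 and 2 with control replicate 2.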

How the results depend on the processing

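Comparisons against the second chromosome and the counts of called genes on 3L and X were added after the data were seen. The number of called probesets, 62, was 27 with the lowest 60% left out, where fewer probesets were tested, and 232 with array weights. It was 0 with a plain Student test, which gave 968 at an unadjusted p under 0.05, and 267 at a linear fold of at least 1.5 without a test; the 232 and the 267 held all 62. With 1 array left out it was between 12 and 84 (17, 12 and 27 without mutant replicates 1, 2 and 3, and 84, 31 and 20 without control replicates 1, 2 and 3). Fewer arrays were fitted in each case, and the cause of the rise to 84 was not tested. Without control replicate 1, 47 of the 62 were shared. Called genes on 3L, 28, were 11 with the lowest 60% left out, 88 of 184 with array weights, and between 6 and 36 with 1 array left out (6 of 12 called genes without mutant replicate 1). On X they were 4 with array weights and 1 to 2 with 1 array left out.

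The replicate block gave 28 called probesets, of which 25 were among the 62, with 16 called genes on 3L, and 1 list (muscle) past camera's threshold. Same-numbered arrays had correlations of 0.053, -0.19 and 0.32, so not every pair was over 0.1. Mutant replicates 1 and 2 and control replicates 1 and 2 did not correlate best with their own number. Pairing by number was therefore not shown, but 3 arrays per group are too few to exclude it. No camera call of a chromosome class changed under the block.

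The X difference stayed between -0.059 and -0.022 with 1 array left out. Its camera call was lost without mutant replicate 1 (-0.026) and control replicate 1 (-0.022), and with no filter (-0.024), where the p passed before adjustment over the 3 classes and not after. The pericentric difference lay between 0.050 and 0.127 with 1 array left out and was 0.048 with the class widened to more genes per arm, and camera's call, at a p adjusted over the 3 classes, was kept under the alternatives run except the symbol list (0.053), which passed only before adjustment. With an estimated correlation its p was under 0.05 only without mutant replicate 3 (p = 0.0408). The chromosome 4 difference was between -0.066 and 0.068 with 1 array left out and -0.0045 with the lowest 60% left out. It passed camera's threshold without mutant replicate 3 (0.068) and, with the sign turned, missed it after adjustment without mutant replicate 1 (-0.066). With an estimated correlation p was 0.607 and 0.569. Lists past camera's threshold, 0, were 3 with array weights (pericentric by symbol, proteasome and, with the sign turned, mitochondrial respiration, -0.092) and between 1 and 5 with 1 array left out, where muscle and detoxification each passed in 4 of 6 fits, larval cuticle and mitochondrial respiration in 2, and fat body, hemocyte, proteasome and the pericentric symbol list in 1, none with an estimated correlation. The muscle and detoxification fits that passed with 1 array left out all kept control replicate 1. The lowest medians with 1 array left out were 0.040 for muscle and -0.038 for detoxification. The cause was not tested where none is named. Of 312 values of 25 named genes under the alternatives, 213 stayed called, 99 did not pass and 0 changed sign; their adjusted p-values were between 1.1e-04 and 0.256. The roX1 and roX2 level and its alternatives were not run. Low signal limits the dim genes: the Y-linked and most male germline probesets lay below the filter.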

Other observations

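On control replicate 1, of 11262 tested probesets, 294 lay at least 2-fold from the mean of the other arrays, 280 of them lower. The largest of these among named genes include the trypsin gene lambdaTry (-4.48 on the log2 scale), the cuticle genes Cpr47Eg (-4.40) and Lcp65Ag3 (-4.07), and Nplp2 (-3.27). The other arrays had between 38 and 144 such probesets. Its list medians, as differences from the 6-array mean, were -0.41 for muscle, -0.32 for detoxification, -0.29 for larval cuticle (0.42 on mutant replicate 3), -0.15 for gut (0.16 on control replicate 3), -0.26 for mitochondrial respiration and 0.21 for the ecdysone response. These genes were chosen after their values were seen. Control replicate 2 had an immune response median of 0.32, against -0.095 to -0.041 on the others.

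Other called genes, named after their values were seen, include the homeobox gene mirr (log2 change 1.03), where a second tested probeset had 1.03 (limma adjusted p = 0.0615), the clock gene cwo (0.64, with 0.21 on its second tested probeset), the NuRD subunit gene simj (1.22), the dihydropteridine reductase gene Dhpr (-0.87) and sgl, the UDP-glucose dehydrogenase gene (-0.66). Probesets of 1 gene often disagreed. A probeset of the junction gene pyd had -2.23, while the other 4 had -0.28 to 0.025. For the Hox gene Antp 1 probeset had -1.55 and the other 0.23, and for CG3857, the called X-linked gene, the second tested probeset had -0.060. Of 12 other tested probesets of genes with a called probeset, 10 changed in the same direction and 1 of them by at least 0.5 times as much. Brighter probesets of pyd and Antp were not called, so these genes are not among the 47 called genes. The 11 called probesets with no gene name here had log2 changes from -1.504 to 1.85.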
